A study of Ganoderma lucidum with 6 samples.

How the data were processed

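Expression was measured by RNA sequencing on the Illumina platform in 6 samples of Ganoderma lucidum mycelia, 3 grown on ammonium sulfate and 3 on sodium nitrate, all at day 3, per the labels. Messenger RNA was isolated from total RNA, per the labels' protocols. The aligner, the counting tool, the genome build and the annotation version are not given in the sources used here, and neither is whether counting used strand.

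The authors deposited 1 table with 1 row per gene. It holds raw read counts per gene and sample, per the file headers, and their totals differ between samples. It also holds TPM and FPKM values that the authors computed, per the file headers. TPM values sum to 1000000 in each sample. Tests used the counts, levels are FPKM as deposited, and TPM were not used further. The table gives positions on scaffolds and, for part of the genes, a KOG description (4997 genes), GO identifiers (7069 genes) and a KEGG entry (1849 genes). No reference genome was used, so exons and introns are not described. Gene length, where used below, is a relative value inferred from the counts and FPKM of these same libraries. GO identifiers come without names, and names given for them are general knowledge.

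Samples were grouped by their titles. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr and robust estimates, on all 6 samples without a block, at a Benjamini-Hochberg adjusted p under 0.05. Positive values mean higher in nitrate. The standard error of a log2 fold change was derived from the test's F statistic. The biological coefficient of variation was 0.248, with 4 residual degrees of freedom.

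Before the data were examined, 23 gene lists were fixed as word patterns on product descriptions. The descriptions turned out to be KOG names, which name no nitrate or nitrite reductase, so 19 lists of GO identifiers were added after the annotation columns were seen and before any test. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. KEGG sets of 10 to 300 tested genes were tested in the same way. With an estimated correlation, none of the 5 fixed lists, 2 GO lists or 6 KEGG sets called by camera remained called. The number of sets at an unadjusted p under 0.05 was then 2 of 23, 1 of 19 and 1 of 186. For the sugar transporter list p rose although its estimated correlation was below 0 (-0.12, camera p = 0.00917 preset and 0.0558 estimated). A call lost under that setting is therefore not by itself evidence of shared spread. Fry, which does not compare a set with other genes, called 11 fixed lists, 2 GO lists and 0 KEGG sets (62 at an unadjusted p under 0.05). Fixed lists that fry alone called, all lower, included nitrate assimilation, plant cell wall hydrolases and the tricarboxylic acid cycle. The others were sulfate assimilation, secreted peptidases, and hydrophobins, mating and meiosis. After values had been seen, 697 GO terms and 124 KOG names were tested in the same way. Camera called 18 and 6 of them, and 0 with an estimated correlation (11 and 5 at an unadjusted p under 0.05).

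Genes were named by a rule fixed at the same time. It took the 5 largest increases and 5 largest decreases with a product description, no overlap between groups and at least 5 FPKM in the higher group. It also took up to 3 called genes of smallest adjusted p from each core list and up to 2 from each other list, and genes of nitrate reduction, nitrate transport and nitrogen regulation whatever their p. The last part was applied through GO identifiers, and the second also to the added GO lists. No gene carried any of the 4 nitrate or nitrite transport identifiers looked up. Part of the genes under the rule are given by the counts of their lists alone. Genes outside the rule are said to have been chosen after their values were seen.

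Alternatives were RLE size factors, no filter on low counts, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and with pseudocounts of 0.1 and 0.01, the replicate number as a block, each library left out, and a 2-fold threshold. The limma fits used genes of at least 1 FPKM in 3 libraries, and their fold changes are on the log2(FPKM + pseudocount) scale.

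A count of 3 in a library, the limit that a count of 0 allows, corresponds to 0.109 to 0.150 per 1000000 counts of the total. Such limits cover counting error only.

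The steps were tested on simulated data with the means, dispersions and totals of the real samples over 11993 genes, 200 of them changed. For this comparison 34.3% of genes changed 2-fold and 91.8% of those changed 4-fold were called, all in the right direction, with 8 calls among unchanged genes. With no gene changed there were 0 calls by edgeR. A set of genes raised together was called by camera, and none of the unchanged sets was. Simulated genes were drawn independently, without the spread that real genes share. False calls of sets of correlated genes were therefore not tested. Fewer genes were changed than the 1874 called in the real data, so the share recovered there may differ.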

Results

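RNA sequencing measured transcript levels in wild-type mycelia of Ganoderma lucidum, a wood-decaying basidiomycete grown for its polysaccharides and triterpenoids. The cultures were sampled at day 3, with ammonium sulfate as the nitrogen source in 3 libraries and sodium nitrate in the other 3. The comparison asks which genes differ between the ammonium salt and nitrate. The salts also differ in sulfate and sodium, so a difference cannot be credited to the nitrogen form alone. The series title speaks of silencing the transcription factor AreA, and no sample analysed here is labelled as silenced. Total gene counts were 24059697, 26719060 and 27604895 in ammonium replicates 1 to 3, and 24325351, 24767602 and 19979528 in nitrate replicates 1 to 3. Of 16113 genes in the table, 2823 had a count of 0 in every library and 11993 passed the filter for testing. The tested genes held 99.98% of all counts. Levels below are FPKM, as mean ± SD over the 3 libraries of a group, and fold changes are log2 values of nitrate over ammonium with their standard errors. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

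On nitrate, the gene with the nitrate reductase identifier, GL22281-G, the ammonia permease GL22186-G and the permease GL20717-G were higher than on ammonium. The Fe2+/Zn2+ transporter GL21849-G, the multicopper oxidase GL17009-G and the C-8 sterol isomerase GL22516-G were lower. At an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 1874 genes differed, of which 899 were higher and 975 were lower in nitrate. At least a 2-fold difference was seen in 1096 of them, 532 higher and 564 lower. The 3 libraries of a group did not overlap those of the other in 4435 tested genes, or 36.98%, where chance gives 10%. Leaving out 1 library moved the count by over 1.5 times in 4 of 6 cases. It was 794 without ammonium replicate 2, 655 without ammonium replicate 3, 1133 without nitrate replicate 2 and 701 without nitrate replicate 3.

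Among described genes without overlap between the groups and with at least 5 FPKM in the higher one, the largest increase was that of GL20717-G, of the family of uridine, thiamine and allantoin permeases, on scaffold 11 at 708256 to 710613. It stood at 0.973 ± 0.373 FPKM in ammonium and at 92.5 ± 11.4 FPKM in nitrate (log2 fold change 6.56 ± 0.33, SE, n = 3 and 3, adjusted p = 0.000132, edgeR). An inorganic phosphate transporter, GL25963-G, was higher by 4.45 ± 0.52 (SE), and an amine oxidase, GL22585-G, by 4.02 ± 0.37. A cytochrome P450 of the CYP3/CYP5/CYP6/CYP9 group, GL31403-G, went from 28.4 ± 3.93 to 335 ± 87.8 FPKM. The amino acid transporter GL23088-G completed the 5 largest increases, at 2.36 ± 0.404 and 26.2 ± 6.56 FPKM. The largest decrease was that of GL21849-G, an Fe2+/Zn2+ regulated transporter, on scaffold 17 at 912475 to 914124. Its level was 679 ± 161 FPKM in ammonium and 26.2 ± 6.39 FPKM in nitrate (log2 fold change -4.71 ± 0.30, adjusted p = 0.000292). P450 genes of the CYP4/CYP19/CYP26 group took the next places, with log2 fold changes of -4.55 ± 0.39 for GL31763-G and -4.26 ± 0.33 for GL21117-G. The model of GL31763-G overlaps another gene model, so its reads could not be told apart from its neighbour's. The multicopper oxidase GL17009-G went from 562 ± 124 to 56.1 ± 24.1 FPKM, and the serine carboxypeptidase GL16427-G fell by 3.29 ± 0.31 on the log2 scale. All of these calls held without any single library.

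Nitrate assimilation reduces nitrate to nitrite and nitrite to ammonium. GL22281-G, the gene with the GO identifier for NADPH-dependent nitrate reductase, lies on scaffold 19 at 588136 to 592352. It stood at 4.93 ± 0.369 FPKM in ammonium and 51.3 ± 3.36 FPKM in nitrate (log2 fold change 3.37 ± 0.15, SE, adjusted p = 9.45e-05, edgeR). GL29837-G, with the identifier for nitrite reductase, lies on scaffold 1 at 184500 to 189374 and was 18.7 ± 2.75 and 41.3 ± 5.53 FPKM (1.14 ± 0.19, adjusted p = 0.00795). The other gene models with that identifier, GL23893-G and GL28160-G, adjoin on scaffold 3 and had counts of 0 in every library. Of 9 tested genes with the GO identifier for nitrate assimilation, 2 rose and none fell, and the other 7 did not pass. Besides GL28706-G, these were the sulfite oxidase-type genes GL19627-G, GL23860-G and GL23629-G and the undescribed GL27036-G, GL20790-G and GL30599-G, with adjusted p-values from 0.164 to 0.517. In fits added after seeing the data, GL27036-G, GL20790-G and GL23629-G passed with the within-group axis as a covariate (adjusted p = 0.0356, 0.00217 and 0.0108). GL23629-G, which was higher, and GL30599-G, which was lower, passed without both libraries at the ends of that axis (adjusted p = 0.000318 and 0.0444). Of the 9 genes, 5 were higher and 1 was lower with the covariate, and 3 and 2 without both ends. The axis was taken from the same data, so p-values of these added fits can be too small. GL22281-G and GL29837-G were also the 2 that passed when p was adjusted over the list alone, and the set was called higher by camera with a preset correlation (adjusted p = 0.0132). That call was lost with an estimated correlation (adjusted p = 0.823) and without ammonium replicate 1 (adjusted p = 0.175). None of the 4 tested genes of the fixed nitrate assimilation list, whose descriptions are of molybdenum cofactor synthesis, passed the edgeR test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2, and DESeq2 called 0. With the within-group axis as a covariate, 2 were called lower.

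**Figure D1:**
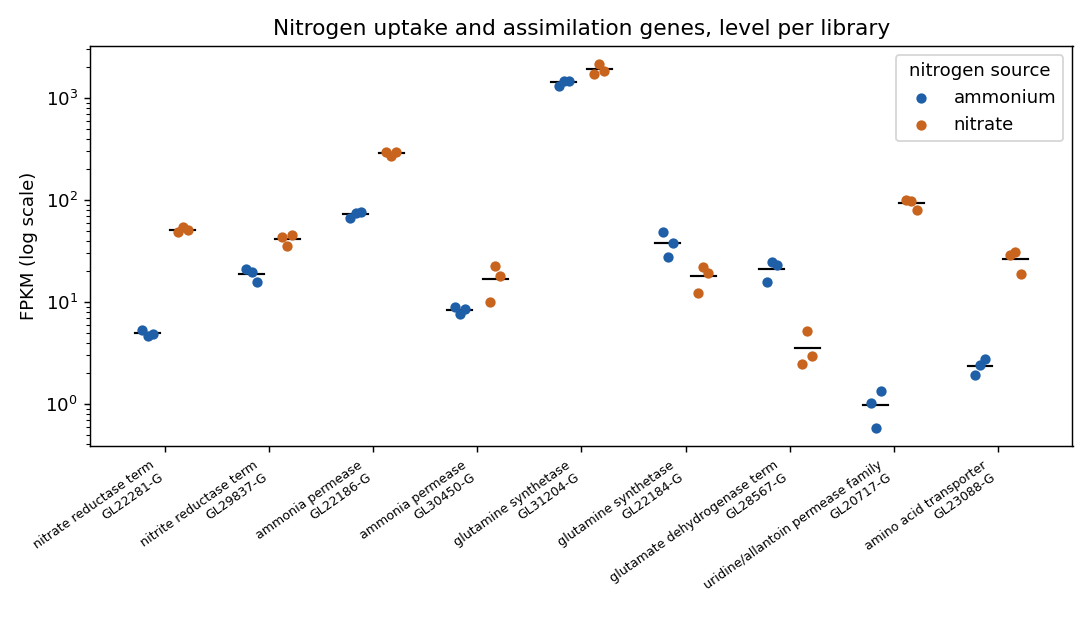
FPKM on a log scale in each library for 9 nitrogen genes. Points are libraries, 3 per nitrogen source, and black lines are group means. The nitrate reductase gene GL22281-G lies at about 51.3 FPKM in nitrate and 4.93 in ammonium, and the abundant glutamine synthetase GL31204-G did not pass the test.

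Among 9 tested genes of ammonium uptake and assimilation, 2 were higher and 2 were lower, with the same counts adjusted over the list alone. The ammonia permease GL22186-G, which carries ammonium across the plasma membrane, rose from 72.0 ± 5.25 to 287 ± 15.1 FPKM (log2 fold change 1.98 ± 0.18, adjusted p = 0.00074). A second ammonia permease, GL30450-G, was 8.29 ± 0.63 and 16.8 ± 6.38 FPKM (adjusted p = 0.0385). It passed the threshold in none of the fits that left out ammonium replicate 1, 2 or 3 or nitrate replicate 2 or 3 (adjusted p = 0.059 to 0.128). Glutamine synthetase joins ammonium to glutamate. The less abundant glutamine synthetase GL22184-G, on scaffold 19 at 174698 to 176934 with the permease GL22186-G at 182509 to 184453, fell from 38.1 ± 10.8 to 17.8 ± 4.92 FPKM (adjusted p = 0.0234). It missed the threshold without ammonium replicate 3 or nitrate replicate 3 (adjusted p = 0.0738 to 0.0807). The abundant glutamine synthetase GL31204-G, named after its values were seen, stood at 1419 ± 103 and 1913 ± 212 FPKM (adjusted p = 0.167, and 0.0244 with the within-group axis as a covariate, a fit added after seeing the data). The other member called lower was a folylpolyglutamate synthase, GL19435-G, a folate enzyme that the list's wording took in, named after its values were seen. Its call (adjusted p = 0.0411) was lost without any 1 of the 6 libraries (adjusted p = 0.0526 to 0.151). By GO identifier, 3 of 13 such genes were higher and 2 lower, and the median and mean were below 0 while camera's direction was up. Besides the genes above they were GL22373-G, a major facilitator permease named after its values were seen, and GL28567-G, with the identifier for glutamate dehydrogenase. The call of GL22373-G was lost without ammonium replicate 1, 2 or 3 or nitrate replicate 3 (adjusted p = 0.0502 to 0.101). GL28567-G fell by 2.59 ± 0.32 on the log2 scale. Its model overlaps the HSP70 gene GL24688-G, at 4560 ± 70.7 and 1929 ± 507 FPKM, so its reads could not be told apart from that gene's. Neither list was called by camera.

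Transporters and enzymes for other nitrogen sources formed the fixed list with the smallest camera p. Of 33 tested members, 11 were higher and 1 was lower, or 13 and 3 when adjusted over the list alone. Besides GL20717-G and GL23088-G, the amino acid transporter GL23068-G rose from 5.65 ± 1.71 to 60.8 ± 17.9 FPKM, and the urea transporter GL22272-G from 2.06 ± 0.733 to 9.78 ± 4.28 FPKM. These last examples were named after their values were seen. Camera with a preset correlation called the list higher (adjusted p = 1.29e-06), in each of the 6 fits without 1 library as well. With an estimated correlation its adjusted p was 0.287. In the 6 fits without 1 library, 9 to 13 members were called higher. The lower member was an amino acid transporter, GL21744-G, named after its values were seen, and it passed in 1 of these fits, that without nitrate replicate 2 (adjusted p = 0.0528 to 0.123 in the others).

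No tested regulator of the fixed list of GATA factors and nitrogen regulators was called. GATA factors are zinc-finger proteins, and fungal nitrogen regulators belong to them. The 5 tested members comprised GATA-type factors GL21693-G, GL25876-G, GL23175-G and GL26054-G and the nitrogen permease regulator GL24863-G, with log2 fold changes from -0.34 to 0.63. The nearest to the threshold was GL25876-G, at 27.7 ± 2.5 and 42.9 ± 7.94 FPKM (adjusted p = 0.0775). At an unadjusted p under 0.05 only GL25876-G passed, none passed when adjusted over the list alone, and DESeq2 called 0. With the within-group axis as a covariate, a fit added after seeing the data, GL25876-G and GL21693-G passed (adjusted p = 0.0062 and 0.0464). Without both libraries at the ends of that axis, GL23175-G passed (adjusted p = 0.00791). By construction these fits take out spread within groups, so such p-values can be too small. GL28706-G, which carries GO identifiers for both nitrate assimilation and regulation of nitrogen utilization, stood at 9.8 ± 2.76 and 7.1 ± 4.14 FPKM (adjusted p = 0.541, and 0.0454 and 0.00191 in those added fits). GL28559-G, a protein kinase with the latter identifier, had an adjusted p of 0.787, and of 0.000596 without both ends of the axis. The table's descriptions do not name AreA, so none of these genes is identified with it here.

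Genes of sugar nucleotide supply, which make the precursors of cell wall and exported polysaccharides, had called members in both directions. Of 26 tested, 3 were higher and 1 was lower, the same over the list alone. That is a similar share to the 1874 called among all 11993 tested genes. Fold changes were above 0 in 13 members and below 0 in 13. UDP-glucose pyrophosphorylase, GL25739-G, which makes the donor for glucan chains, rose from 276 ± 67.8 to 663 ± 123 FPKM (log2 fold change 1.24 ± 0.24, adjusted p = 0.0133). Without ammonium replicate 2 or nitrate replicate 3 it missed the threshold (adjusted p = 0.0521 to 0.0635). Glucose-6-phosphate isomerase, GL22245-G, which leads glucose 6-phosphate into glycolysis, fell from 92.0 ± 22.8 to 37.6 ± 9.26 FPKM (adjusted p = 0.0121, and 0.0567 without nitrate replicate 3). A UDP-glycosyltransferase, GL25279-G, was 4.1 ± 1.1 and 9.33 ± 2.59 FPKM. It passed the threshold in neither the fits without ammonium replicate 2 or 3 nor those without nitrate replicate 2 or 3 (adjusted p = 0.0785 to 0.0875). UDP-N-acetylglucosamine pyrophosphorylase, GL30088-G, which makes the donor for chitin, was named after its values were seen. It stood at 654 ± 56.8 and 1152 ± 190 FPKM, and it passed in the fit without nitrate replicate 1 but in no other fit that left out a library (adjusted p = 0.0582 to 0.128). Phosphoglucomutase, GL24280-G, also chosen after its values were seen, was 60.5 ± 23.5 and 28.8 ± 13.8 FPKM (adjusted p = 0.0864). It passed by DESeq2 (adjusted p = 0.0239) and without nitrate replicate 2 (adjusted p = 0.0429). Without ammonium replicate 2 or nitrate replicate 3 none of the 26 was called higher, and without nitrate replicate 3 none was lower.

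Of 10 tested genes of glucan and chitin synthesis, 1 was higher and 2 were lower, or 2 and 2 adjusted over the list alone. A 1,3-beta-glucan synthase, GL15036-G, rose from 3.26 ± 0.33 to 8.26 ± 0.845 FPKM (adjusted p = 0.00413), and a chitin synthase, GL28060-G, fell from 3.83 ± 0.549 to 1.55 ± 0.38 FPKM (adjusted p = 0.00765). Glycogen synthase, GL24971-G, was lower at 24.4 ± 2.36 and 12.0 ± 3.35 FPKM, a call that was lost without ammonium replicate 3 or nitrate replicate 3 (adjusted p = 0.0603 to 0.0614). Among 22 genes of glucan and chitin hydrolysis, the chitinase GL25941-G alone was called, and it passed in 1 of the 6 fits without a library, that without nitrate replicate 3 (adjusted p = 0.0558 to 0.125 in the others, and 0.07 to 0.0939 by limma). Adjusted over that list alone, no member passed. By the GO identifiers of chitinase, 3 of 23 were higher and none was lower, also over the list alone. They were GL25941-G, GL29255-G and GL18544-G. GL29255-G missed the threshold without ammonium replicate 3 or nitrate replicate 3 (highest adjusted p = 0.0564), and GL18544-G without ammonium replicate 2 or 3 or nitrate replicate 3 (highest 0.108). By the GO identifiers of glucan and chitin synthesis, 2 of 18 were higher and 1 was lower. By those of sugar nucleotides, 1 of 13 was higher and 2 were lower, or 1 and 4 over the list alone. Without 1 library each count was 1 to 2 in the former and 0 to 2 in the latter. Camera called none of these lists, nor the fixed list of sugar nucleotides.

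In the mevalonate and sterol list, the route that also leads to triterpenoids, 1 of 15 tested genes was higher, 6 were lower and 8 did not pass, or 1 and 7 adjusted over the list alone. The C-8 sterol isomerase GL22516-G fell from 189 ± 8.84 to 57.0 ± 12.8 FPKM (log2 fold change -1.74 ± 0.18, adjusted p = 0.00131). Mevalonate pyrophosphate decarboxylase, GL25304-G, fell from 209 ± 21.8 to 81.8 ± 7.02 FPKM, and acetyl-CoA acetyltransferase, GL26574-G, from 247 ± 3.99 to 104 ± 20.5 FPKM. Named after their values were seen, oxidosqualene-lanosterol cyclase GL18675-G fell by 1.41 on the log2 scale and C-4 sterol methyl oxidase GL23074-G by 1.30. HMG-CoA reductase, GL24088-G, the regulated step early in the route, also named after its values were seen, was 737 ± 255 and 1041 ± 371 FPKM (adjusted p = 0.412, and 0.00764 with the within-group axis as a covariate). The higher member, a geranylgeranyl pyrophosphate synthase, GL24453-G, named in the same way, missed the threshold without ammonium replicate 2 or 3 or nitrate replicate 3 (adjusted p = 0.0527 to 0.063). Camera called the list lower (adjusted p = 0.00302, and in each of the 6 fits without 1 library). With an estimated correlation its adjusted p was 0.428. Camera did not call the KEGG sets Steroid biosynthesis and Terpenoid backbone biosynthesis (adjusted p = 0.406 and 0.359). By the GO identifier for ergosterol synthesis, 1 of 22 was higher and 7 were lower, or 1 and 11 over the list alone (camera adjusted p = 0.000996, and 0.826 with an estimated correlation). The strongest of these, GL24664-G, at 68.9 ± 12.4 and 13.0 ± 2.61 FPKM, also carries GO identifiers for siderophore synthesis. The higher gene, a lipase-type GL30230-G named after its values were seen, was called (adjusted p = 0.0492) in none of the 6 fits without 1 library. Leaving out a library gave 4 to 7 lower members of the first list and 4 to 9 of the second, where 7 became 4 without ammonium replicate 2 or 3 or nitrate replicate 3. Of 8 genes with terpene synthase identifiers, GL20733-G and GL20244-G were higher and GL23369-G was lower, at 4.35 ± 0.917 and 0.655 ± 0.0272 FPKM, and the list was not called. GL20244-G was named after its values were seen, and the 2 higher calls were lost without ammonium replicate 2 or 3 or nitrate replicate 3, and that of GL20244-G without nitrate replicate 2 too (adjusted p = 0.0521 to 0.0818). The median of this list was above 0 and its mean below.

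**Figure D2:**
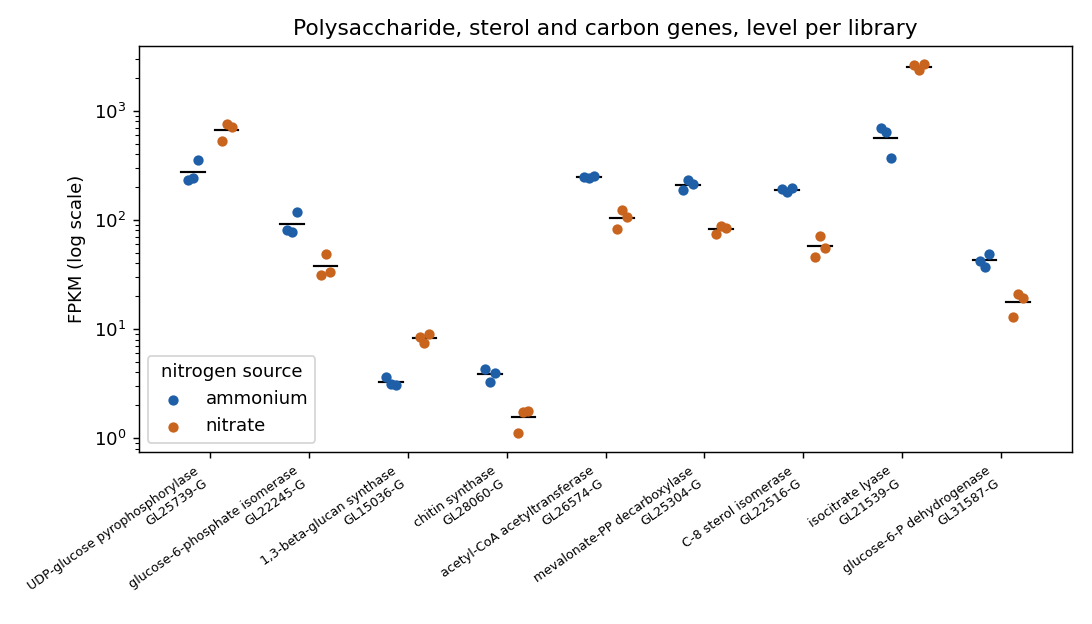
FPKM on a log scale in each library for genes of polysaccharide supply, sterol synthesis and carbon metabolism. Points are libraries, 3 per nitrogen source, and black lines are group means. The C-8 sterol isomerase GL22516-G lies near 189 FPKM in ammonium and 57.0 in nitrate, and isocitrate lyase GL21539-G is higher in nitrate in all 3 libraries.

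The list of the tricarboxylic acid cycle and glyoxylate shunt had 1 higher and 7 lower of 33, and that of glycolysis and gluconeogenesis 1 higher and 7 lower of 34. Neither was called by camera, with adjusted p-values of 0.0573 and 0.164. The KEGG set Glycolysis / Gluconeogenesis, of 32 tested genes, had as many higher as lower and was not called (adjusted p = 0.691). The one higher member of the former was isocitrate lyase, GL21539-G, the first enzyme of the glyoxylate shunt, which rose from 567 ± 177 to 2539 ± 174 FPKM (log2 fold change 2.16 ± 0.27, adjusted p = 0.00283). Lower members were 3-isopropylmalate dehydrogenase GL31360-G, a leucine synthesis enzyme, and alcohol dehydrogenase GL31436-G, at log2 fold changes of -2.27 ± 0.28 and -1.14 ± 0.18. The higher member of the glycolysis list, a short-chain dehydrogenase GL27927-G named after its values were seen, passed in none of the 6 fits without 1 library (adjusted p = 0.0533 to 0.147). Of 10 genes of NADPH supply, 3 were lower and none was higher. Glucose-6-phosphate dehydrogenase, GL31587-G, the entry to the pentose phosphate pathway, fell from 42.5 ± 5.73 to 17.6 ± 4.21 FPKM. 6-phosphogluconate dehydrogenase, GL30487-G, was 191 ± 33.4 and 101 ± 17.4 FPKM, and it missed the threshold without ammonium replicate 2 or 3 or nitrate replicate 3 (adjusted p = 0.0502 to 0.0959). The least abundant, a transketolase, GL26014-G, named after its values were seen, missed it without ammonium replicate 3 or nitrate replicate 1, 2 or 3 (adjusted p = 0.056 to 0.0996). Without ammonium replicate 2 or 3 or nitrate replicate 3 the lower members numbered 3, 4 and 3 in the tricarboxylic acid cycle list and 3, 3 and 2 in the glycolysis list, which had 4 without nitrate replicate 1. Over each list alone, 1 higher and 8 lower members passed for the tricarboxylic acid cycle, 1 and 7 for glycolysis, and 0 and 4 for NADPH supply.

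Camera called the sugar transporter list and the amino acid synthesis list lower (adjusted p = 0.0422 and 0.0115), and with an estimated correlation neither was called (adjusted p = 0.428 and 0.556). Of 6 sugar transporters, 2 were lower, GL21351-G at 101 ± 15.5 and 24.9 ± 5.07 FPKM and GL30249-G at 11.3 ± 2.4 and 3.52 ± 0.992 FPKM. The list's call was also lost without ammonium replicate 1, nitrate replicate 2 or nitrate replicate 3 (highest adjusted p = 0.0894). By the GO identifiers of sugar proton symporters, 2 of 21 were higher and 1 was lower. Camera did not call that list (adjusted p = 0.767), and none of it was lower without ammonium replicate 2 or 3 or nitrate replicate 3. Of 39 genes of amino acid and arginine synthesis, 5 were lower and none was higher, led by GL31360-G and the leucine synthesis enzyme 3-isopropylmalate dehydratase GL26795-G, which fell by 0.83 ± 0.15 on the log2 scale. The latter missed the threshold without ammonium replicate 2 (adjusted p = 0.0517). The others were the homoaconitase-type GL29907-G, argininosuccinate lyase GL24849-G and tryptophan synthase GL24792-G, the last pair named after their values were seen. GL29907-G missed the threshold without ammonium replicate 2 or nitrate replicate 3 (highest adjusted p = 0.0566), GL24849-G without ammonium replicate 1, 2 or 3 or nitrate replicate 3 (highest 0.113), and GL24792-G without ammonium replicate 2 or 3 or nitrate replicate 2 or 3 (highest 0.11). Lower members numbered 1 without ammonium replicate 2, 3 without ammonium replicate 3 and 2 without nitrate replicate 3. Adjusted over each list alone, the counts were the same.

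Of 197 tested cytochrome P450 genes, 33 were higher and 24 were lower, or 36 and 29 over the list alone, and camera did not call the list. Higher and lower genes numbered 13 and 16 without ammonium replicate 2, 12 and 13 without ammonium replicate 3, 21 and 19 without nitrate replicate 2, and 13 and 13 without nitrate replicate 3. Among 15 ligninolytic oxidoreductases, 2 multicopper oxidases were higher and GL17009-G was lower. The clearer of the higher ones, GL29490-G, at 24.7 ± 13.5 and 80.7 ± 15.9 FPKM, missed the threshold without ammonium replicate 2, nitrate replicate 2 or nitrate replicate 3 (adjusted p = 0.074 to 0.0902), with the within-group axis as a covariate (adjusted p = 0.0647) and without both ends of that axis (adjusted p = 0.173). The other, GL21497-G, whose model overlaps another, passed in none of the 6 fits without 1 library (adjusted p = 0.0694 to 0.155). GL17009-G carries the GO identifier for ferroxidase, an enzyme of iron uptake. For this list the median was above 0, and the mean and camera's direction were below. Of 10 plant cell wall hydrolases, an alpha-galactosidase, GL30909-G, and a beta-mannosidase, GL26515-G, were lower and none was higher. Of 79 secreted peptidases, 6 were higher and 14 were lower, or 12 and 16 over the list alone. Without ammonium replicate 2 or 3 or nitrate replicate 2 or 3, the higher members numbered 1, 1, 1 and 2, and the lower members 8 without ammonium replicate 3 and 7 without nitrate replicate 3. The aspartyl protease GL18792-G fell from 42.8 ± 9.32 to 5.38 ± 0.863 FPKM (adjusted p = 0.000292), and the carboxypeptidase GL21209-G from 87.5 ± 11.4 to 24.7 ± 1.27 FPKM. By the GO identifiers of aspartic peptidases the balance was the other way, with 12 higher and 7 lower of 61, or 17 and 7 over the list alone, and camera did not call that list (adjusted p = 0.767). Its higher members numbered 7 without ammonium replicate 2, nitrate replicate 2 or nitrate replicate 3, and 5 without ammonium replicate 3.

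Of 45 genes of redox and nitrosative defence, 3 were higher and 8 were lower, or 4 and 8 over the list alone. The members with the smallest adjusted p were ferric reductase-type genes, which reduce iron at the cell surface or make superoxide. GL24941-G fell from 44.5 ± 3.87 to 8.98 ± 0.542 FPKM and GL16044-G from 303 ± 38.7 to 115 ± 15.6 FPKM (adjusted p = 0.000292 and 0.00424). The higher members were glutathione S-transferases GL25817-G and GL16746-G and the ferric reductase-type GL17398-G, named after their values were seen. GL25817-G missed the threshold without ammonium replicate 3 (adjusted p = 0.0527), GL16746-G without ammonium replicate 2 or 3 or nitrate replicate 2 or 3 (highest 0.0982), and GL17398-G without any 1 of the 6 libraries (0.0539 to 0.128). The lower members numbered 4 without ammonium replicate 3 or nitrate replicate 3. ATP sulfurylase, GL25330-G, was the single called gene of 6 for sulfate assimilation, lower at 27.6 ± 5.74 and 15.0 ± 3.26 FPKM, and it missed the threshold without ammonium replicate 3 or nitrate replicate 3 (adjusted p = 0.0807 to 0.0875). None of the 13 genes of the sodium, pH and osmotic response was called by the main edgeR test, with 1 at an unadjusted p under 0.05. DESeq2, limma and the filter of 50 counts each called 1 higher. In fits added after seeing the data, 1 was higher and 3 were lower with the within-group axis as a covariate. Without both ends of that axis, 1 was higher and 6 were lower. Camera called none of these lists.

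Chaperones, proteasome subunits and autophagy genes, fixed as markers of stress, had 5 higher and 18 lower of 106, with the same counts over the list alone. The endoplasmic reticulum chaperone GRP94, GL24667-G, fell from 2427 ± 399 to 739 ± 198 FPKM (log2 fold change -1.74 ± 0.25, adjusted p = 0.00494), and the HSP90 co-chaperone GL20648-G from 367 ± 15.0 to 192 ± 22.2 FPKM. The higher members, named after their values were seen, were DnaJ-type chaperones GL25992-G and GL23026-G, autophagy factors GL22261-G and GL22912-G and the proteasome subunit GL16236-G. Of these, GL25992-G and GL22912-G passed in none of the 6 fits without 1 library, and GL23026-G in 1. Each of the 5 lost its call without ammonium replicate 2, without ammonium replicate 3 and without nitrate replicate 3 (highest adjusted p = 0.15). The lower members numbered 3 in each of those fits, and 8 without nitrate replicate 1 or 2. Camera called the list lower (adjusted p = 0.0343), and the call was lost with an estimated correlation (adjusted p = 0.574) and without ammonium replicate 1 or nitrate replicate 1 (highest adjusted p = 0.104). Markers of other hyphal states, in the list of hydrophobins, mating and meiosis, had 1 higher and 3 lower of 16. Camera did not call the set, while fry called it lower (adjusted p = 0.0121). A pheromone exporter-type ABC transporter, GL21032-G, fell from 60.4 ± 11.0 to 21.5 ± 2.74 FPKM. The others were the meiosis-related methyltransferase GL30369-G, which was higher, and GL31506-G and GL25631-G, of a checkpoint kinase and the anaphase-promoting complex, which were lower and were named after their values were seen. GL30369-G missed the threshold without ammonium replicate 3 (adjusted p = 0.056), and the lower pair without ammonium replicate 2 or 3 or nitrate replicate 2 or 3, and GL31506-G without nitrate replicate 1 too (highest adjusted p = 0.114). GL16371-G, with the GO identifier that hydrophobins carry, was in the GO list of cell wall structural proteins and rose from 4.76 ± 2.21 to 208 ± 158 FPKM (adjusted p = 0.0021). Of 84 ribosomal protein genes, 1 was called, GL27514-G, which was lower, and none over the list alone. Its call was lost without ammonium replicate 2 or 3 or nitrate replicate 2 or 3 (adjusted p = 0.0541 to 0.0874), 3 were lower without ammonium replicate 1 and 2 without nitrate replicate 1, and DESeq2 called 4 lower. Camera called none of the GO lists apart from those of nitrate assimilation and ergosterol. In those of peroxidase, of cellulose and xylan breakdown and of chitinase, median and mean had opposite signs.

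**Figure D3:**
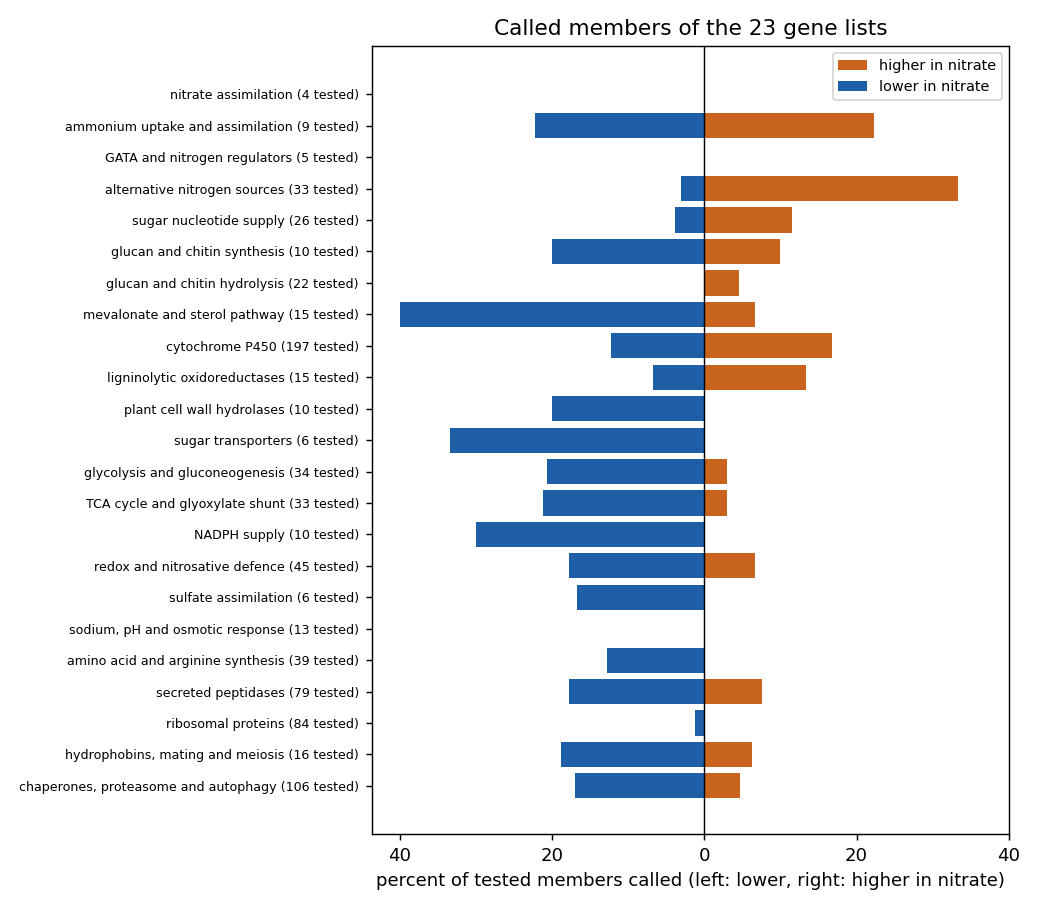
Percent of tested members called at an adjusted p under 0.05 in each of the 23 fixed lists, to the right for genes higher and to the left for genes lower in nitrate. Bars start at 0 and the number tested stands beside each list, so 11 of 33 members of the list of alternative nitrogen sources lie to the right.

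Among 186 KEGG pathway sets of the table, camera with a preset correlation called 6, all lower in nitrate. They were DNA replication, Cell cycle, Meiosis - yeast, Cell cycle - yeast, Proteasome and Mismatch repair, which share members. Of 28 tested DNA replication genes, 12 were lower and none was higher (adjusted p = 5.3e-05). The replication helicase GL21153-G and the MCM6 licensing factor GL31495-G, named after their values were seen, fell by 1.45 and 1.08 on the log2 scale. With an estimated correlation none of the 6 was called (adjusted p = 0.981 for each). Proteasome and Mismatch repair also lost their calls without ammonium replicate 1 or nitrate replicate 1 (highest adjusted p = 0.0678 and 0.171).

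The first principal component held 53.3% of the variance of log2 CPM and separated the 2 nitrogen sources. The second held 29.9% and lay within the groups, with ammonium replicate 1 at 41.4 and replicates 2 and 3 at -18.8 and -18.6, and nitrate replicate 1 at -43.3 and replicates 2 and 3 at 14.4 and 24.9. Every pair of libraries differed by more than counting noise, with chi-square values per gene of 36.3 or more, so no library was counted as a copy of another.

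**Figure D4:**
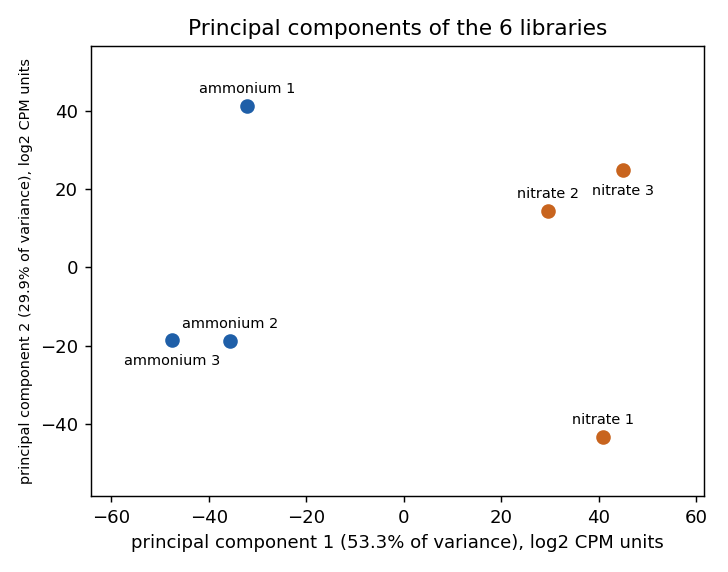
Scores of the 6 libraries on the first 2 principal components of log2 CPM over 11993 genes. Blue points are ammonium and orange points nitrate libraries, which the first component (53.3% of variance) separates and the second (29.9%) does not.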

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

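The fits with the within-group axis, without the libraries at its ends, camera without 1 library, and components of log2(FPKM + 1) were chosen after seeing the data. The 1874 calls stayed within 1.5 times under RLE factors, no filter, the filter of 50 counts, DESeq2 and limma with each pseudocount (1546 to 2545), and the share of higher genes stayed between 46.9% and 51.0%. Requiring 2-fold left 1096. Leaving out 1 library gave 655 to 1946 calls, with fewer samples in each fit. The within-group axis as a covariate gave 4909 calls, of which 1865 were among the 1874, and leaving out ammonium replicate 1 and nitrate replicate 1 together gave 4898. Both take out spread within groups by construction, so their p-values can be too small and neither is independent evidence. The deviations of same-numbered libraries correlated at -0.66, -0.35 and -0.46, so equal replicate numbers showed no shared shift. With 3 libraries per group and 1 axis holding most of the spread, this cannot tell whether same-numbered samples were handled together. With the replicate number as a block 225 genes were called, and camera then called 5 fixed lists, 2 GO lists and 6 KEGG sets, as without the block. Of 23 fixed lists, camera called 5, with 0 under an estimated correlation, 11 by fry, 2 without both ends of the axis, and 3 to 8 without 1 library. Of 19 GO lists it called 2, with 0 under an estimated correlation, 1 without both ends, and 1 to 3 without 1 library. Of 186 KEGG sets it called 6, with 0 under an estimated correlation and 4 to 9 without 1 library. The first component held 55.8% on log2(FPKM + 1). For these changes the cause was not tested. Of 115 called genes that the naming rule or later choices took, of which the text names a part, none changed direction under any alternative here, and 114 kept their call with RLE factors, 115 with DESeq2, 105 with limma, 42 with the block and 75 to 103 without 1 library. At the totals, dispersions and 3 libraries per group of these data, 34.3% of simulated 2-fold changes were called. There 200 genes were changed and genes were drawn independently. The share was not computed at other depths, so how far depth limits it is not known.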

Other observations

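The tests of the within-group axis, of the iron term with the axis as a covariate and with an estimated correlation, and of other sample splits were chosen after their results were seen. The neighbour tests and the length test of the iron term were set before. Iron and copper uptake was not among the fixed lists. Besides the Fe2+/Zn2+ transporter GL21849-G and the ferroxidase-term gene GL17009-G, several genes named after their values were seen were lower in nitrate. The copper transporter GL22574-G went from 251 ± 26.9 to 50.1 ± 11.7 FPKM, and GL21193-G, with a GO identifier for siderophore iron import, fell by 2.92 on the log2 scale. A peptide synthetase-type gene with siderophore identifiers, GL24538-G, fell by 1.75 and a second Fe2+/Zn2+ transporter, GL23315-G, by 1.03. The last missed the threshold without ammonium replicate 2 or 3 or nitrate replicate 3 (adjusted p = 0.1 to 0.12). In the other direction, the mitochondrial Fe2+ transporter GL30755-G rose from 15.5 ± 2.11 to 68.3 ± 8.51 FPKM.

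Undescribed genes were among the largest changes. GL20732-G went from 2917 ± 52.4 FPKM in ammonium to 62.2 ± 13.6 FPKM in nitrate (log2 fold change -5.57 ± 0.24), and GL30392-G, with GO identifiers of bacterial cell wall breakdown, from 52.6 ± 12.3 to 764 ± 145 FPKM. Both were named after their values were seen. GL21539-G, isocitrate lyase, lies on scaffold 15 in a run of 4 adjacent genes that rose, with a glycolate oxidase, GL21586-G, and P450 genes GL31775-G and GL31774-G at log2 fold changes of 2.49, 2.05 and 1.09. On scaffold 4 a run of 4 that fell holds an isovaleryl-CoA dehydrogenase, GL19834-G, a major facilitator permease, an aminotransferase and an arginase, GL24613-G. The arginase call was lost without ammonium replicate 2 or 3 or nitrate replicate 2 or 3 (adjusted p = 0.0567 to 0.101).

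The iron homeostasis identifier had 1 higher and 12 lower of 33 tested genes, the smallest camera p of 697 GO terms (adjusted p = 0.000622). The axis scores sum to 0 within each group, so the fit with the axis as a covariate (adjusted p = 0.000338) could move the difference little (mean log2 fold change -0.60 and -0.62) and does not test this, and a spread along the axis stays open. Gene length, as inferred from counts and FPKM, is argued against as the whole cause. Camera gave an adjusted p of 0.00176 after the trend on that length was taken out. With an estimated correlation the adjusted p was 0.993, and the term's correlation of 0.128 lay above an upper bound of 0.0627 from 1000 random sets. So shared chance spread of its genes may contribute to the set call. That setting called 0 of the 697 terms, so the lost call cannot be credited to shared spread alone. The calls of single genes do not rest on the set test, and lower iron demand or supply in nitrate cultures stays untested.

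Chance arrangement is argued against. Adjacent genes were called in the same direction more often than chance arrangement gives, 256 pairs of 10601 against a mean of 136 in 10000 permutations within 10 classes of mean count, a ratio of 1.89 (permutation p = 0.0001, the smallest they can give). Reads shared by overlapping or abutting models are argued against as the whole cause, since pairs at least 1000 bp apart gave a ratio of 1.98 (permutation p = 0.0001). Reads shared by neighbouring copies of a gene are argued against as the whole cause by a ratio of 1.54 (permutation p = 0.0036). That ratio came from the 1996 pairs of described genes with different KOG names. It is lower than over all pairs, but those include undescribed genes. Whether copies account for part therefore cannot be told. Pairs that meet both limits were not tested, so overlap and copies acting together stay open. A candidate explanation is shared control of neighbouring genes, which these data do not test.

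Within both groups the libraries spread along one axis that held 62.4% of the variance within groups, with ammonium replicate 1 at -0.56 and nitrate replicate 1 at 0.58. Of 84 ribosomal protein genes, 77 lay on its negative side, as did 18 of 19 cell wall structural protein genes and 29 of 107 transcription factor genes, against 53.2% of all tested genes. Length, as inferred from counts and FPKM, may contribute. A smooth curve of it explained 10.9% of the variance of the genes' axis values, and 20.3% in the 5998 genes with higher counts. That argues against this length as the whole cause. Thinning to equal totals left the axis as it was (cosine of 1.00, share of 61.7%). A setting that moves nothing cannot tell whether the number of counts is a cause. Totals at the ends were 24059697 and 24325351. Within each group the library with the smallest total had the lowest score (-0.56 for ammonium replicate 1, -0.37 for nitrate replicate 3). Depth, or something that went along with it, therefore stays open. Culture stage and RNA handling stay open, and no biological explanation was tested. For the 1874 calls, 10 splits of the samples are too few for a share under 0.05. The real split gave 1874 calls, and the highest of the others 117.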
